A study of Mus musculus with 6 samples.

How the data were processed

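Total RNA from whole ear skin of 6 mice, aged 10 to 12 weeks, was labelled with biotin and hybridised to Affymetrix mouse gene arrays, 1 mouse per array, per the labels' protocols. The authors deposited log2 values made by RMA (robust multi-array average: background correction, quantile normalisation between arrays and a summary per probe set), per the series' design text. The scale was read from the values, which run from 1.60 to 13.9. The software and version used for RMA are not given in the sources used here, and the submitters' processing notes name the mouse build mm8 without its role. RMA sets all arrays to nearly one distribution, so a change shared by most genes would be lost, and it compresses differences of dim genes. The deposited table holds no background measure, so no gene could be called present or absent, and no slide or scan date was used here.

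The table holds 35556 probe sets. The platform annotation lists 1 gene symbol for 21789 of them, several for 1621, and does not list 12146, which are unnamed here. Of the Entrez identifiers, 21698 were found in a RefSeq gene table of assembly GRCm38.p6, which was used only for names and for which genes neighbour each other, and 91 were not. Probe sets with 1 symbol were kept, and of several probe sets of a gene the one with the highest mean over all arrays, which gave 19938 genes. No gene was left out for a low level. Members of gene families such as Sprr2 are close in sequence, and probes may be shared between them.

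The groups were 3 CLEC4C-DTR and 3 littermate control mice, as labelled, and the replicates are separate animals. No pair of arrays held identical values. CLEC4C-DTR was compared with littermate control by limma 3.58.1 (lmFit and eBayes, with statmod 1.5.0, R 4.3.3), two-sided, with no covariate and with Benjamini-Hochberg adjustment over all genes. All adjusted p-values of genes are from that limma fit, and a gene was called at 0.05, with a 2-fold threshold as the design text states. With 3 against 3, an exact permutation test of one gene cannot go below 0.1. Changes are given as CLEC4C-DTR minus control on the log2 scale, with limma's SE.

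Before the data were examined, 34 gene lists (22 of cell types, 12 of pathways), the tests and the rule for naming genes were fixed. Lists with 5 or more measured members, 32 in all, were tested with limma's camera at a preset correlation of 0.01 between genes, with adjustment over the 32 lists. The test was repeated with a correlation estimated for each list, and with fry. Genes were named by 3 rules: Siglech, Bst2, Ccr9 and Hbegf whatever their values, the 12 largest rises and 12 largest falls among called genes whose groups do not overlap, and up to 4 members of each list with the smallest p. Genes named outside these rules are said to be. Older symbols of list members were matched through synonyms only where the symbol is not that of another current gene, a correction made after a first look at the data that took 1 wrongly matched gene out of the plasmacytoid dendritic cell list. Some lists share genes, such as Cxcl5 in both the acute inflammatory and the IL-17 lists.

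On simulated data with the spread of these arrays, the limma step recovered 24 of 50 genes changed by 0.5, 38 of 50 changed by 1, 50 of 50 changed by 2 and 49 of 50 changed by 3 on the log2 scale, with 6 false calls among 167. The simulated genes varied independently, while genes on the arrays vary together. The false calls of the simulation therefore do not measure the error of the calls below. Alternatives were other scalings of the arrays, filters on dim genes, other moderation of variances, array weights, other probe set rules, a block for the replicate number, and each array left out in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.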

Results

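Gene expression was measured in ear skin of 6 mice at the end of a contact hypersensitivity protocol with FITC (fluorescein isothiocyanate), a small reactive dye that sensitises skin. Of these, 3 mice carried the CLEC4C-DTR transgene and 3 were littermate controls, with 1 mouse and 1 challenged ear per array. The transgene places the diphtheria toxin receptor under control of CLEC4C, a gene of human plasmacytoid dendritic cells, so that toxin can remove cells that express it. All 6 mice received 200 ng of diphtheria toxin on days -1, 1, 3 and 5. FITC at 0.5% in acetone and dibutyl phthalate was painted on the shaved abdomen on days 0 and 2 (100 µL) and on the right ear on day 6 (20 µL). Only FITC-treated ears were analysed here, and the time from challenge to collection is not given in the sources used here. The median log2 value over all probe sets lay between 6.17 and 6.23 on every array. The number of arrays, 3 per group, limits the precision of every value below.

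The comparison of CLEC4C-DTR with control skin asks how challenged ears differ between the groups after toxin. No unchallenged ear and no CLEC4C-DTR mouse without toxin was among the samples. Effects in the ear, on sensitisation and of the genotype itself can therefore not be told apart. In the skin of CLEC4C-DTR mice, 17 of 20 activated keratinocyte genes and 15 of 25 acute inflammatory cytokine and chemokine genes rose. Both lists passed the list test, but not with an estimated correlation (adjusted p = 0.227 and adjusted p = 0.233). The largest rise was that of Sprr2f, a small proline-rich protein of the cornified envelope, at a log2 value of 10.05 to 11.35 in the 3 CLEC4C-DTR mice and 4.98 to 6.87 in the controls (log2 difference of 4.65, SE 0.50, adjusted p = 0.00937). The antimicrobial defensin Defb3 was 21.5-fold higher (adjusted p = 0.0121) and the neutrophil chemokine Cxcl3 17.1-fold higher (adjusted p = 0.00937). Falls were smaller, and the largest was that of the epithelial metallothionein Mt4, 5.33-fold (log2 -2.41, SE 0.28, adjusted p = 0.00937).

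Of 19938 genes tested with limma, 1858 passed an adjusted p of 0.05, with 998 higher and 860 lower in CLEC4C-DTR skin. The balance of directions turned with the scaling, with 1064 higher and 738 lower under median centring and 940 higher and 997 lower after a further quantile normalisation. At least a 2-fold difference was found for 408 of these, 333 higher and 75 lower, and at least a 4-fold one for 66 higher and 2 lower. In 6581 genes (33.0%) the 3 values of one group all lay beyond the 3 of the other, against 10% by chance. The count depended on single arrays: it was 466 without CLEC4C-DTR replicate 2, 108 without CLEC4C-DTR replicate 3, 167 without littermate control replicate 1, 1219 without littermate control replicate 2, 67 without littermate control replicate 3 and 2617 without CLEC4C-DTR replicate 1. Across all 6 of these fits 56 genes passed each time, 41 higher and 15 lower. Each of the 1858 genes kept its direction, but this was fixed in advance. The groups did not overlap in any of the 1858, so leaving out 1 array could not turn a direction. The count was 2069 over the 23410 probe sets listed with a gene, 95 when the 12146 unlisted ones were added, and 0 when variances were not moderated across genes, where 4387 genes had an unadjusted p under 0.05 with equal and 3308 with unequal variances.

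**Figure D1:**
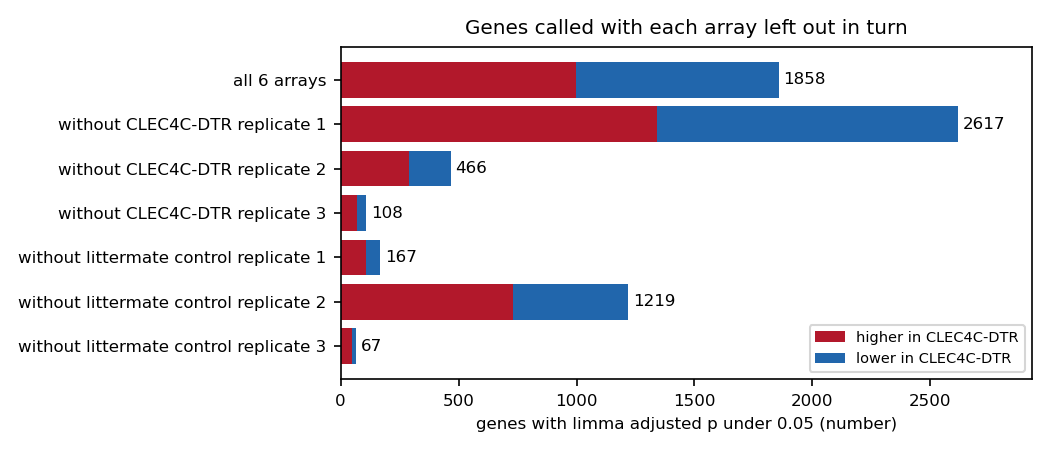
Number of genes with a limma adjusted p under 0.05 (horizontal axis) with all 6 arrays and with each array left out in turn (vertical axis), split into genes higher and lower in CLEC4C-DTR skin. The count was 1858 with all arrays and ranged from 67 without littermate control replicate 3 to 2617 without CLEC4C-DTR replicate 1.

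Among the 12 largest rises were 4 further Sprr2 genes beside the chemokines. Sprr2d rose 15.6-fold, Sprr2e 13.6-fold, Sprr2g 10.4-fold and Sprr2h 9.45-fold. The neutrophil chemokines Cxcl5 and Cxcl2 rose 14.5-fold and 9.77-fold. Ptgs2, the inducible cyclooxygenase, rose 10.7-fold (log2 3.42, SE 0.62, adjusted p = 0.0206), and Trem1, a receptor that amplifies inflammatory signals in myeloid cells, rose 9.65-fold (adjusted p = 0.0213). The non-coding transcript Mirt2 rose 10.2-fold. Sprr2f, Sprr2d, Sprr2h, Cxcl3, Cxcl5 and Mt4 also passed in every fit with 1 array left out.

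The 12 largest falls included keratins and secreted matrix proteins. Krt24 fell by 2.07 on the log2 scale (adjusted p = 0.0351) and Krt15, a keratin of basal cells and hair follicle stem cells, by 1.59 (adjusted p = 0.0193). The protease inhibitors Serpina3b and Serpinb12 fell by 1.97 and 1.83. Bbox1, the last enzyme of carnitine synthesis, fell by 1.93, and the lipoxygenase Alox12e by 1.76. Ogn and Aspn, small leucine-rich proteoglycans of the matrix, fell by 1.65 and 1.57. Dapl1 fell by 1.83, Kazald1 by 1.61 and the guidance molecule Sema3d by 1.54.

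**Figure D2:**
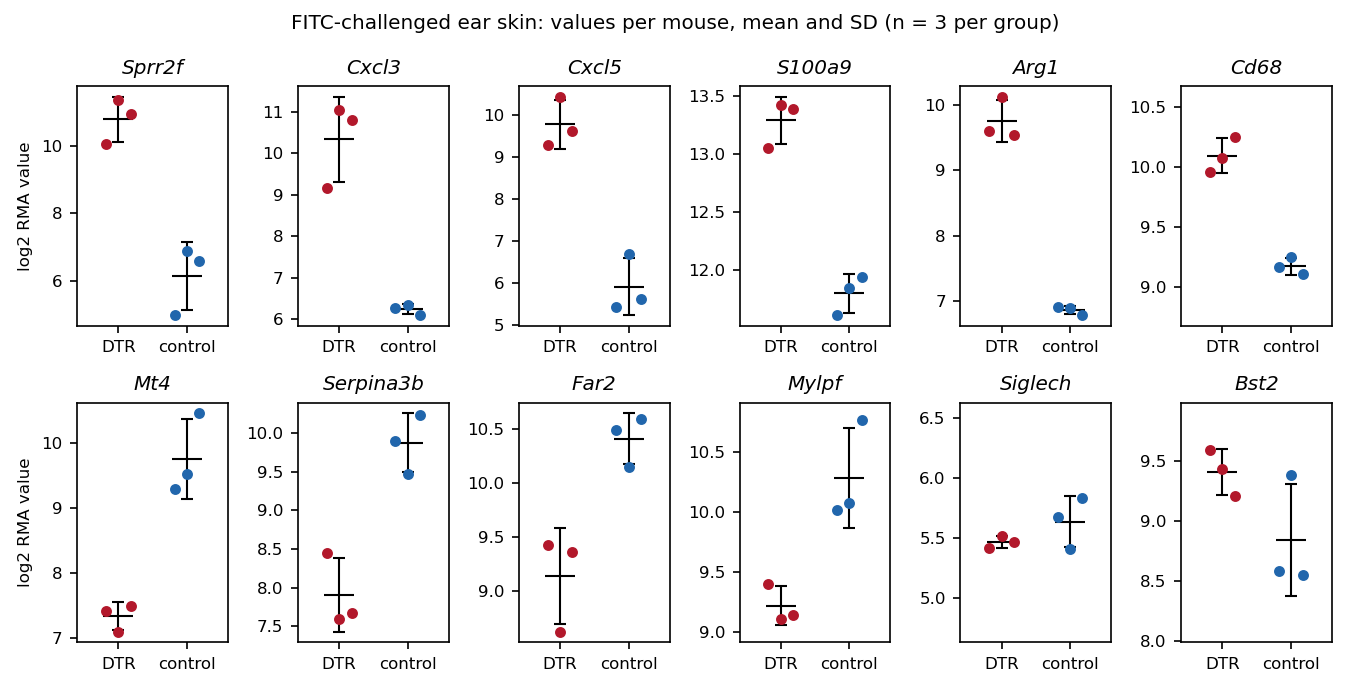
Log2 RMA values (vertical axes) of 12 genes in each mouse, with points for the 3 CLEC4C-DTR and 3 littermate control mice, a bar for the group mean and whiskers of 1 SD. The groups do not overlap for the 10 genes from Sprr2f to Mylpf, and they overlap for Siglech and Bst2.

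Markers of plasmacytoid dendritic cells did not pass the test with all arrays. Siglech, a lectin of mouse plasmacytoid dendritic cells, had a mean log2 value of 5.47 ± 0.05 (SD, n = 3) in CLEC4C-DTR skin and 5.64 ± 0.22 (SD, n = 3) in controls (log2 -0.17, adjusted p = 0.378). Ccr9, a chemokine receptor of these cells, differed by -0.26 (adjusted p = 0.258). The smallest p of the list were those of the transcription factor gene Tcf4, which differed by -0.41 (SE 0.12, adjusted p = 0.0729), and of Smim5, which differed by -0.28 (SE 0.10, adjusted p = 0.113). For both, the 3 CLEC4C-DTR values all lay below the 3 control values. Tcf4 passed without CLEC4C-DTR replicate 1 (adjusted p = 0.0156), and its adjusted p was 0.0517 to 0.320 under the other alternatives. The gene Bst2, which interferon also induces, differed by 0.57 (adjusted p = 0.140), and 1 of the 3 control values lay among those of the CLEC4C-DTR mice. It passed without littermate control replicate 2 (adjusted p = 0.0218), and its adjusted p was 0.0893 to 0.409 under the other alternatives. Of the 13 measured genes of the list limma called 0, also adjusted over the list alone, with 3 at an unadjusted p under 0.05, and 10 had lower and 3 higher values. The calls with single arrays left out were Tcf4 as above and 2 rises without littermate control replicate 2. The list test gave an adjusted p of 0.210, or adjusted p = 0.320 with an estimated correlation and 0.0743 with fry, each toward lower values. Siglech and Ccr9 lay at percentiles 31.2 and 31.5 of mean level among all genes, Tcf4 and Bst2 at 91.1 and 92.5, and the list's median was 44.5. Hbegf, the mouse counterpart of the human growth factor precursor that binds the toxin, rose 2.44-fold (log2 1.29, SE 0.32, adjusted p = 0.0474). Whether its probes also read the transgene was not tested here.

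Genes of activated keratinocytes, which are made by epidermis under injury or inflammation, rose together. Of 20 measured members, 17 rose, none fell and 3 did not pass, and 19 rose adjusted over the list alone. The list test gave an adjusted p of 5.14e-19, and adjusted p = 0.227 with an estimated correlation. Krt17, a stress keratin, rose by 0.92 (SE 0.10, log2) and the cornified envelope gene Sprr1a by 0.90 (SE 0.09, log2). The protease inhibitor Stfa2 rose by 2.72 (SE 0.29, log2). Mean levels of the list, set against the mean of the controls, were 1.47, 2.57 and 2.53 (log2) in CLEC4C-DTR replicates 1, 2 and 3. The number of rises was 8 without CLEC4C-DTR replicate 3, 9 without littermate control replicate 3 and 11 without littermate control replicate 1. The basal keratinocyte list (11 measured) held 1 fall, Krt15, and no rise, with 1 rise and 4 falls adjusted over the list alone, and did not pass (adjusted p = 0.0760). It passed toward lower values with fry (adjusted p = 0.0252) and after a further quantile normalisation (adjusted p = 0.00905), with a range of 0.00905 to 0.320 over all alternatives. Its calls were 1 rise and 4 falls without CLEC4C-DTR replicate 1, and none without CLEC4C-DTR replicate 3 or littermate control replicates 1 or 3, where 4 or 5 members had an unadjusted p under 0.05. In the differentiated keratinocyte list (13 measured) only Tgm1, a crosslinking enzyme of the cornified envelope, changed, rising by 1.57 (adjusted p = 0.0146), also adjusted over the list alone. That list did not pass (adjusted p = 0.627), and its median was 0.06 and its mean -0.02 (log2). It held 1 fall beside the rise without CLEC4C-DTR replicate 1, and no call in the same 3 fits as the basal list, with 5, 2 and 2 at an unadjusted p under 0.05.

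Neutrophil genes and acute inflammatory genes were higher in CLEC4C-DTR skin. Of 17 measured neutrophil genes, 12 rose, none fell and 5 did not pass, and 16 rose adjusted over the list alone. The list test gave an adjusted p of 5.26e-13, and adjusted p = 0.233 with an estimated correlation. S100a9 and S100a8, the subunits of calprotectin, rose 2.80-fold and 3.06-fold (adjusted p = 0.00802 and 0.00937), and both passed in every fit with 1 array left out. The neutrophil product Retnlg rose 7.58-fold and the gelatinase Mmp9 4.83-fold. List means were 1.00, 2.39 and 2.20 (log2) above the mean of the controls in CLEC4C-DTR replicates 1, 2 and 3. Fewer rose with single arrays left out: 2 without CLEC4C-DTR replicate 3 or littermate control replicate 3, 3 without littermate control replicate 1 and 4 without CLEC4C-DTR replicate 2. The 2 rises were S100a8 and S100a9 in each case, with 15 members at an unadjusted p under 0.05. Of 25 acute inflammatory cytokine and chemokine genes, 15 rose, none fell and 10 did not pass, with 21 rising adjusted over the list alone (list adjusted p = 2.39e-15, and adjusted p = 0.233 with an estimated correlation). Among them Ccl3, a chemokine for myeloid cells, rose 6.94-fold (adjusted p = 0.0143). Here the same 4 fits gave 2, 2, 3 and 8 rises.

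The IL-17 and IL-36 response list followed the same direction. Of 18 measured members 8 rose, none fell and 10 did not pass, and 12 rose adjusted over the list alone (list adjusted p = 6.09e-11, and adjusted p = 0.233 with an estimated correlation). Defb14, an antimicrobial defensin, rose by 2.82 (SE 0.32, log2), the iron-binding lipocalin Lcn2 by 1.72 (SE 0.19, log2) and Ccl20, the ligand of Ccr6, by 1.22 (SE 0.17, log2). Leaving out CLEC4C-DTR replicate 3, littermate control replicate 1 or littermate control replicate 3 left 3 rises, and leaving out CLEC4C-DTR replicate 2 left 4.

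Monocyte and macrophage genes rose as well. Of 14 measured members 10 rose, none fell and 4 did not pass, with 12 rising and 1 falling adjusted over the list alone (list adjusted p = 8.55e-10, and adjusted p = 0.233 with an estimated correlation). The lysosomal protein Cd68 rose by 0.92 (SE 0.10, log2), the mannose receptor Mrc1 by 1.57 (SE 0.21, log2), the complement gene C1qa by 1.13 (SE 0.20, log2) and Cd14, a co-receptor for lipopolysaccharide, by 3.09 (SE 0.50, log2). List means were 0.81, 1.00 and 1.26 (log2) above the mean of the controls in CLEC4C-DTR replicates 1, 2 and 3. Of 15 conventional dendritic and Langerhans cell genes, 5 rose and none fell, with 6 rising adjusted over the list alone (list adjusted p = 0.00217, and adjusted p = 0.227 with an estimated correlation). The 4 with the smallest p were Fscn1, Itgax, Ccr7 and Clec9a, and the fifth, Clec10a, was named after its values were seen. Fscn1, an actin-bundling protein of mature dendritic cells, rose by 0.98 (SE 0.10, log2) and Ccr7, the receptor that guides them to lymph nodes, by 0.69 (SE 0.16, log2). Of 14 MHC class II presentation genes, 8 rose and none fell, also adjusted over the list alone (list adjusted p = 2.43e-05, and adjusted p = 0.233 with an estimated correlation). H2-Eb1 rose by 0.57, Cd74, the invariant chain, by 0.63 and the costimulatory molecule Cd80 by 1.85 (log2). Without littermate control replicate 3, calls were made for 2 monocyte and macrophage genes and 1 dendritic cell gene, and limma called 0 class II genes, with 8 at an unadjusted p under 0.05. Monocyte and macrophage rises numbered 1, 2 and 5 without CLEC4C-DTR replicate 3, littermate control replicate 1 and CLEC4C-DTR replicate 2. For class II genes these fits gave 0, 0 and 4, with 10, 9 and 8 at an unadjusted p under 0.05. The dendritic cell list held 1 rise in every fit with an array left out except that without CLEC4C-DTR replicate 1, which gave 4.

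The type 2 response list, chosen because FITC in dibutyl phthalate is used as a type 2 sensitiser, was mixed. Of 26 measured members 7 rose, 1 fell and 18 did not pass, with 8 rising and 1 falling adjusted over the list alone (list adjusted p = 1.72e-05, and adjusted p = 0.227 with an estimated correlation). Arg1, an arginase of alternatively activated macrophages, had the lowest p of all genes and rose 7.39-fold, from 6.86 ± 0.06 (SD, n = 3) to 9.75 ± 0.32 (SD, n = 3) on the log2 scale (SE 0.15, adjusted p = 0.00120). The chemokine Ccl8 rose by 1.55, its receptor Ccr8 by 0.92 and the decoy receptor Il13ra2 by 0.56 (log2). The 1 member that fell was Il5, the eosinophil growth factor, by 0.36 on the log2 scale (adjusted p = 0.0368), and it was named after its values were seen. Il13 differed by 0.55 (adjusted p = 0.0583). With arrays left out there was 1 rise without littermate control replicate 3, 3 without CLEC4C-DTR replicate 3 or littermate control replicate 1 and 4 without CLEC4C-DTR replicate 2, and Il5 passed in none of the 6 fits.

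Genes induced by type I interferon were higher in part. Of 23 measured members 6 rose, none fell and 17 did not pass, with 10 rising adjusted over the list alone. The list test gave an adjusted p of 1.24e-07, and adjusted p = 0.320 with an estimated correlation and 0.148 with fry. Oas3 and Oas2, antiviral oligoadenylate synthetases, rose by 1.29 (SE 0.28, log2) and 1.20 (SE 0.27, log2), Zbp1, a nucleic acid sensor, by 1.16 (SE 0.25, log2) and Oasl1 by 0.73 (SE 0.14, log2). List means in the controls were 0.04, 0.44 and -0.48 (log2) around their own mean, and 0.50, 0.95 and 0.45 above it in CLEC4C-DTR replicates 1, 2 and 3. Without littermate control replicate 2, 10 members rose. Leaving out CLEC4C-DTR replicate 2, CLEC4C-DTR replicate 3, littermate control replicate 1 or littermate control replicate 3, limma called 0 members, with 10, 13, 10 and 11 at an unadjusted p under 0.05. Of 13 measured type I interferon genes limma called 0, also adjusted over the list alone, with 0 at an unadjusted p under 0.05 (list adjusted p = 0.298, and 0.0458 toward lower values with fry). Of 16 interferon gamma response genes limma called 0, with 8 at an unadjusted p under 0.05 and 3 rising adjusted over the list alone, and the list test passed (adjusted p = 4.85e-05, and adjusted p = 0.324 with an estimated correlation and 0.168 with fry). Those 3 were Socs1, Cd274 and Irf1. This count rested on 1 control: 8 members rose without littermate control replicate 2, whose list mean was 0.56 (log2) above that of the controls, against -0.17 and -0.39 for replicates 1 and 3, and 1 rose without CLEC4C-DTR replicate 1.

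All 13 measured T cell genes had higher values in CLEC4C-DTR skin. Of these, 2 rose, the adhesion molecule Cd2 by 1.18 (adjusted p = 0.0102) and the costimulatory receptor Icos by 1.37 (adjusted p = 0.0293), and 10 rose adjusted over the list alone (list adjusted p = 1.33e-07, and adjusted p = 0.233 with an estimated correlation). Of 13 regulatory T cell genes, 5 rose and 1 fell, with 6 and 2 adjusted over the list alone (list adjusted p = 0.00612, and adjusted p = 0.233 with an estimated correlation and 0.204 over genes above the median level). The inhibitory receptor Ctla4 rose by 1.75, Il2ra, the alpha chain of the IL-2 receptor, by 1.28 and Tnfrsf9 by 0.82 (log2). Foxp3 rose by 0.39 (adjusted p = 0.0277) and Ikzf2 fell by 0.53 (adjusted p = 0.0287), both named after their values were seen. Of 15 NK and cytotoxic cell genes only Nkg7 rose (2 adjusted over the list alone, list adjusted p = 0.0699, and 0.00268 to 0.508 under the alternatives). That count was 4 without littermate control replicate 2, 2 without CLEC4C-DTR replicate 1 and 0 with any other array left out, where 3 to 5 had an unadjusted p under 0.05. Of 11 B and plasma cell genes and of 11 eosinophil and basophil genes limma called 0, also adjusted over the list alone, with 2 of each at an unadjusted p under 0.05 (list adjusted p = 0.765 and 0.0845). The eosinophil and basophil list had an adjusted p of 0.0140 to 0.423 under the alternatives, with 2 rises without littermate control replicate 2 and 1 without CLEC4C-DTR replicate 2, and the B and plasma cell list had 1 fall without CLEC4C-DTR replicate 1. Of 13 mast cell genes only Hdc, the histamine-forming enzyme, rose, 5.02-fold (adjusted p = 0.0164), also adjusted over the list alone, and the list did not pass (adjusted p = 0.627). Hdc did not pass without CLEC4C-DTR replicate 3, littermate control replicate 1 or littermate control replicate 3. Leaving out littermate control replicate 3, limma called 0 T cell and 0 regulatory T cell genes, with 9 and 7 at an unadjusted p under 0.05. T cell rises numbered 4 without CLEC4C-DTR replicate 1 and 1 without CLEC4C-DTR replicate 3 or littermate control replicate 1. Of the regulatory T cell list, 2 rose without littermate control replicate 1 and limma called 0 without CLEC4C-DTR replicate 3, with 7 at an unadjusted p under 0.05. The mast cell proteases Mcpt4, Cma1 and Cpa3, named after their values were seen, differed by 0.04, 0.09 and -0.23 (log2).

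Anti-inflammatory regulators held rises and a fall. Of 20 members 7 rose and 1 fell, with 13 and 2 adjusted over the list alone (list adjusted p = 1.32e-05, and adjusted p = 0.227 with an estimated correlation). Tgfb1 rose by 0.67, Ebi3 by 0.53 and the checkpoint ligand Pdcd1lg2 by 1.67 (log2), while Tgfb2, named after its values were seen, fell by 0.66 on the log2 scale. Of 21 cell cycle genes 6 rose and none fell, with 18 rising adjusted over the list alone (list adjusted p = 6.09e-11, and adjusted p = 0.233 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase, rose by 0.89 and the mitotic kinase Plk1 by 0.92 (log2). Of 17 oxidative and xenobiotic response genes 6 rose and 2 fell, with 9 and 3 adjusted over the list alone (list adjusted p = 0.00217, and adjusted p = 0.233 with an estimated correlation). The cystine transporter Slc7a11 rose by 2.61 and Gsta4 by 1.54 (log2), while the quinone reductase Nqo1 fell by 0.63 on the log2 scale, and the second fall was that of Gstm1, named after its values were seen. Of 14 immediate early genes Jun, Ier3 and Atf3 rose, with 5 rising adjusted over the list alone (list adjusted p = 0.000377, and adjusted p = 0.319 with an estimated correlation and 0.136 with fry). Leaving out littermate control replicate 3, limma called 0 members of these 4 lists, with 12, 15, 10 and 6 at an unadjusted p under 0.05, and without CLEC4C-DTR replicate 3 also 0, with 13, 15, 11 and 6. Rises in these lists numbered 3, 1, 2 and 0 without CLEC4C-DTR replicate 2, 1, 1, 2 and 0 without littermate control replicate 1, 6, 1, 4 and 2 without littermate control replicate 2, and 11, 12, 8 and 6 without CLEC4C-DTR replicate 1. Where no immediate early gene was called, 5 to 9 had an unadjusted p under 0.05.

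Lists of resident tissue were lower. Of 13 sebaceous gland genes 8 fell, none rose and 5 did not pass, with 9 falling adjusted over the list alone (list adjusted p = 5.75e-07, and adjusted p = 0.233 with an estimated correlation). Far2, which makes fatty alcohols for wax esters, fell by 1.28 (SE 0.22, log2), the desaturase Scd3 by 0.84 (SE 0.12, log2) and Pparg, the nuclear receptor of lipid-forming cells, by 0.63 (SE 0.11, log2). Of 18 skeletal muscle genes 7 fell and none rose, with 15 falling adjusted over the list alone (list adjusted p = 4.95e-08, and adjusted p = 0.319 with an estimated correlation and 0.0605 with fry). The myosin light chains Mylpf and Myl1 fell by 1.06 and 0.61, myoglobin (Mb) by 0.67 and nebulin (Neb) by 0.74 on the log2 scale. Of 13 adipocyte genes Car3, Adipoq and Fabp4 fell, by 1.20, 1.38 and 1.13 on the log2 scale, with 6 falling and 1 rising adjusted over the list alone (list adjusted p = 0.00217, and adjusted p = 0.365 with an estimated correlation, 0.0876 with fry and 0.0586 over genes above the median level). Of 14 cartilage genes Ucma, Cnmd, Col9a3 and Acan fell, with 8 falling adjusted over the list alone (list adjusted p = 0.000142, and adjusted p = 0.255 with an estimated correlation). Of 8 Schwann cell and melanocyte genes the pigment genes Pmel and Tyrp1 fell, with 6 falling adjusted over the list alone (list adjusted p = 0.00146, and adjusted p = 0.233 with an estimated correlation). Of 18 hair follicle genes limma called 0, also adjusted over the list alone, with 2 at an unadjusted p under 0.05 and 17 lower by value. That list test passed (adjusted p = 0.0174, and adjusted p = 0.233 with an estimated correlation and 0.0881 after a further quantile normalisation). Leaving out littermate control replicate 3, 1 sebaceous gland gene fell, and limma called 0 muscle, adipocyte, cartilage and Schwann cell or melanocyte genes, with 13, 7, 7 and 4 at an unadjusted p under 0.05. Falls in these 5 lists, in that order, numbered 3, 0, 0, 0 and 0 without CLEC4C-DTR replicate 2, 1, 0, 0, 0 and 0 without CLEC4C-DTR replicate 3 and 0, 1, 1, 0 and 0 without littermate control replicate 1, and at least 5 members of each list had an unadjusted p under 0.05 in these 3 fits. They numbered 5, 2, 4, 1 and 1 without littermate control replicate 2, where 1 hair follicle gene also fell, and 8, 10, 4, 6 and 4 without CLEC4C-DTR replicate 1. Littermate control replicate 3 was the highest of the 3 for muscle and adipocyte genes: list means in littermate control replicates 1, 2 and 3 were -0.25, -0.09 and 0.34 (log2) around their own mean for muscle and -0.18, -0.16 and 0.35 for adipocyte genes.

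Fibroblast and endothelial lists did not pass (adjusted p = 0.214 and 0.601). Of 15 fibroblast and matrix genes only Pdgfra, a growth factor receptor of fibroblasts, rose, by 0.53 (adjusted p = 0.0298), with 2 rising and 5 falling adjusted over the list alone. Of 13 endothelial genes only Pecam1 rose, by 0.40 (adjusted p = 0.0312), also adjusted over the list alone. With arrays left out, Pecam1 passed only without CLEC4C-DTR replicate 1, where 2 fibroblast and matrix genes rose and 2 fell, and Pdgfra only there and without littermate control replicate 2. Only Alas2 and Slc4a1 of the erythroid list were measured, and neither passed, also adjusted over the list alone. In the list that checks sex, Xist lay between 10.70 and 11.27 (log2) and the Y-linked genes Eif2s3y, Uty and Kdm5d between 2.53 and 4.03 on all 6 arrays, with no call over all genes and 1 fall, Xist, adjusted over the list alone.

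**Figure D3:**
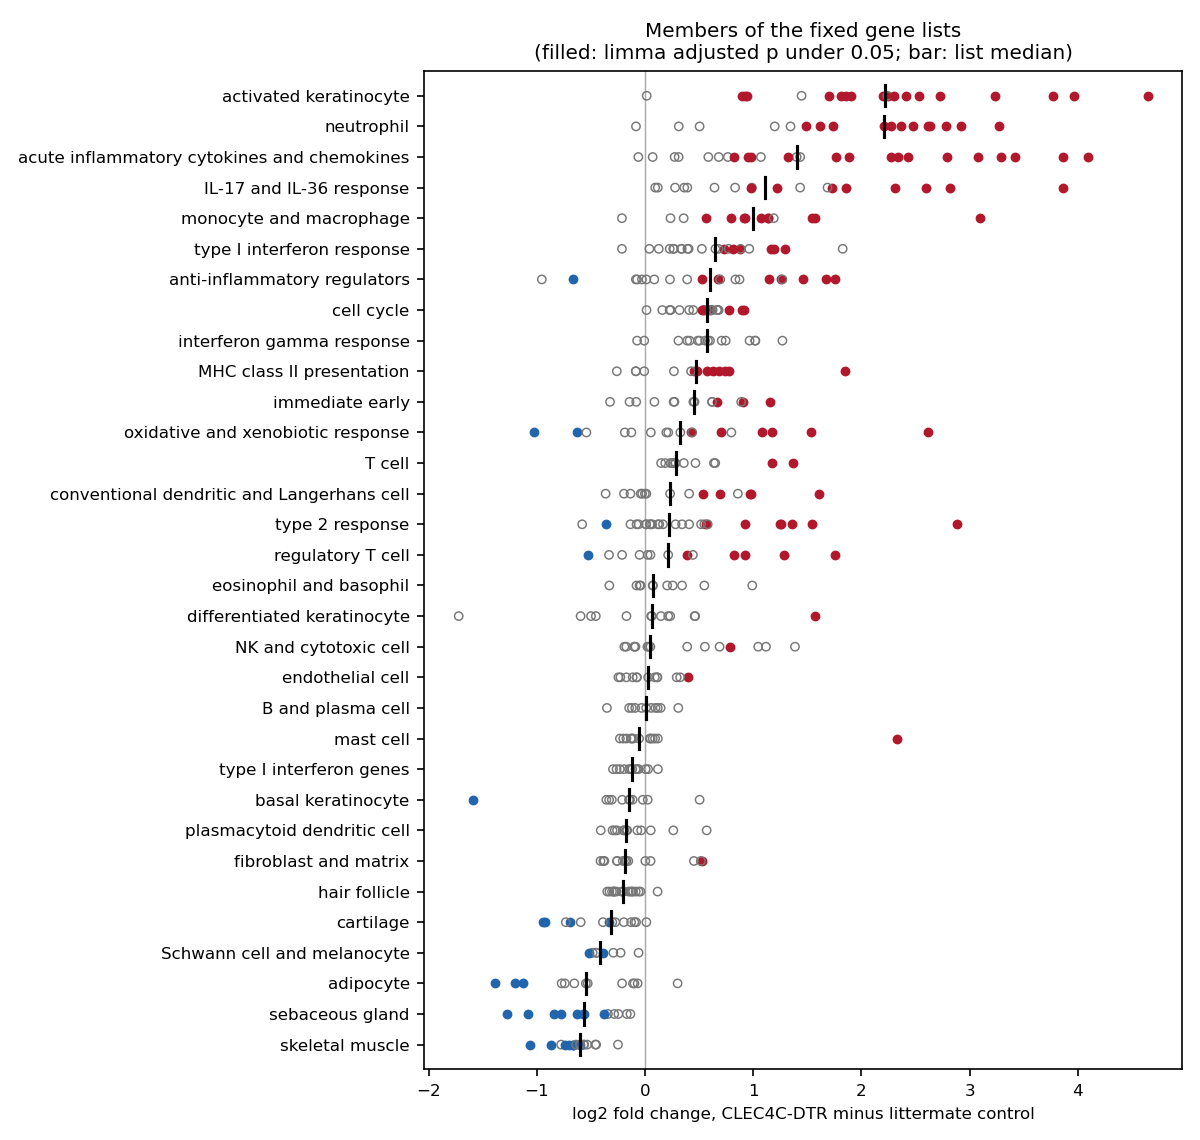
Log2 fold change, CLEC4C-DTR minus littermate control (horizontal axis), of every measured member of the 32 lists tested (vertical axis, ordered by median), with filled points for genes with a limma adjusted p under 0.05 and a bar at each list median. Medians reached 2.22 for activated keratinocyte and 2.21 for neutrophil genes and -0.60 for skeletal muscle genes.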

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

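The tests on the position of CLEC4C-DTR replicate 1, on resident tissue and on plasmacytoid dendritic cell genes were chosen after the results were seen, and the tests on other splits of the arrays before.

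Outside the named genes, 22 probe sets without a listed gene and 1 probe set with several gene symbols passed limma's test when every probe set was tested. They lie outside the comparison of named genes and enter only the count over every probe set.

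Over the 10 ways to split the 6 arrays into 3 and 3, only 1 split, the real one, called as many as 1858 genes, and the highest of the others called 0. For genes changed at least 2-fold, 1 split, again the real one, called as many as 408, and the highest other was 0. With 10 splits no share under 0.05 can be reached. Every other split mixes mice of both groups, so the difference between the groups enters its spread within groups and lowers its calls. The counts of 0 therefore do not show how many calls chance alone would give.

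CLEC4C-DTR replicate 1 lay nearest the controls: on the first principal component (70.1% of the variance) it was at 7.58, against 39.3 and 28.3 for replicates 2 and 3 and -32.8 to -17.9 for the controls. Its values correlated across genes at 0.99049 with CLEC4C-DTR replicate 3, 0.99035 with littermate control replicate 2 and 0.987 with CLEC4C-DTR replicate 2. Its mean correlation was 0.9887 with its own group and 0.9865 with the controls, too close to place it in either group. Every pair of controls correlated at 0.992 or more. Whether it is a control array under a wrong label stayed open by a first criterion, the median position of an array over the genes called without it. The scale was 0 at the mean of the controls left and 1 at that of the CLEC4C-DTR mice left. Replicate 1 was at 0.532 over 2617 genes, and the highest control, littermate control replicate 2, at 0.303 over its own 1219 genes. A criterion on list means replaced the first. By that one a wrong label is argued against, as replicate 1 lay beyond all controls by more than their range in 13 of the 23 lists that pass without it, by 1.31 (log2, range 0.257) in the activated keratinocyte list, though the count is weak evidence: littermate control replicate 2 did so against the other 2 controls in 12 of 23 lists, by 0.223 in that list. A weaker reaction in that mouse may remain, untested, and its median position was 0.301 for immediate early, 0.398 for neutrophil and 0.795 for monocyte and macrophage genes.

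The lists of muscle, sebaceous gland, adipocyte, cartilage and Schwann cell genes were lower together. If nothing else changed, a lower share of every resident cell type, as infiltrating cells would give, would lower all 10 resident lists alike. With the median of the 10 lists removed from each array, the groups did not overlap in 7 lists, against at most 1 in the other 9 splits. Of these 7 lists 6 were higher and 1, sebaceous gland, was lower. The median lay midway between the sebaceous gland and Schwann cell lists, so these mirror each other (-0.10 and 0.10, log2) and count once. An equal fall in all lists is argued against by the keratinocyte, hair follicle, fibroblast and endothelial lists, which stood higher against that median. Muscle, adipocyte and cartilage lists overlapped, so for them an equal fall stays open. On its own the hair follicle list was lower (list test adjusted p = 0.0174). A lower share of resident cells is not excluded by this. Differences of dim genes are compressed by RMA, and Tgm1, Pdgfra and Pecam1 rose, so a lower share need not lower all lists equally. Hair follicle, fibroblast and basal keratinocyte medians were also below 0 (-0.20, -0.19 and -0.15, log2). A smaller share of muscle in the samples would lower all muscle genes by one factor. The SD of their changes was 0.174 against a median SE of 0.163, which cannot decide it. Muscle genes varied together between mice (estimated correlation 0.846), and this shared part enters the SE but not the SD between genes. Differences in how the ears were cut and lower expression within these tissues may both remain, and neither was tested.

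No plasmacytoid dendritic cell gene was lower past the threshold with all arrays. A candidate explanation is that these transcripts lie low in whole skin. The list does not decide it: 8 of its 13 members lay below the median level of all genes, Siglech and Ccr9 among them, while the list's median percentile was 44.5 and Tcf4 and Bst2 lay at 91.1 and 92.5. Values of whole skin do not show which cells gave the Tcf4 and Bst2 signal, so their level does not speak against this explanation. Whether plasmacytoid dendritic cells were fewer in the CLEC4C-DTR skin may not be readable from these arrays, and it was not tested otherwise.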

How the results depend on the processing

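Genes changed numbered 1858, and ranged from 67 to 2617 with each array left out; genes changed at least 2-fold numbered 408, with a range of 40 to 624. With no moderation of variances, equal or unequal, both counts were 0 (limma found 5437 genes at an unadjusted p under 0.05, and the unmoderated models 4387 and 3308). With every probe set tested they were 95 and 51, where the prior degrees of freedom of the moderation were 2.65 against 4.02 for named genes. Over the 23410 probe sets listed with a gene, a setting chosen after seeing the data, they were 2069 and 431 (prior degrees of freedom 3.77), so the drop came with the 12146 unlisted probe sets; why these lower it was not tested. At least 1.5-fold gave 1027 genes, and an unadjusted p under 0.05 with at least 2-fold gave 471. Other scalings, filters, array weights, probe set rules and trend with robust moderation gave 1725 to 2416 genes, within 1.5 times. The planned pseudocount for linear values was not run, as the values are log2. Whether the replicate numbers pair the mice stayed open. Deviations of same-numbered mice correlated at -0.06, 0.22 and 0.10, with 2 pairs over the minimum of 0.1 that was set. Of the 6 arrays, 3 correlated best with their own number, and 3 mice per group are too few to settle it. The replicate block gave 2084 genes and 451 at least 2-fold. With an estimated correlation, none of the 22 passing lists passed: the neutrophil list had an adjusted p of 0.233, the type I interferon response list 0.320 and the type 2 response list 0.227, and 0 of the 19 other passing lists remained. fry, a test of a set's own direction, gave 0.148 for the type I interferon response list and called 19 lists. With the preset correlation of 0.01, leaving out any array ended no list call. The tests with an estimated correlation and with fry were not repeated with arrays left out. The NK and cytotoxic cell, eosinophil and basophil, basal keratinocyte and type I interferon gene lists gained a call under some settings, the latter pair toward lower values. The direction turned for lists near 0: differentiated keratinocyte (adjusted p 0.885 over genes above the median level, 0.581 without CLEC4C-DTR replicate 3 and 0.729 without littermate control replicate 2) and B and plasma cell (0.908 at a mean of at least 5 and by fry, 0.906 without CLEC4C-DTR replicate 2 and 0.799 without littermate control replicate 1). Over all arrays left out, turned or not, these lists ran from 0.175 to 0.814 and from 0.512 to 0.906. Changes of gene Uty, gene Kdm5d and gene Eif2s3y, near 0, also turned: Uty to 0.00656 and Kdm5d to 0.0161 under median centring, Kdm5d to 0.0188 under quantile normalisation, and with arrays left out Eif2s3y ran from -0.137 to 0.0565, Uty from -0.0786 to 0.0332 and Kdm5d from -0.0415 to 0.0223; the cause was not tested.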

Other observations

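The gene families and runs of neighbouring genes below were picked after the values were seen, while the test of neighbouring genes of unlike name was written before its result.

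Families of genes were counted and not tested as sets. Of 9 measured Sprr2 genes 8 rose, with a median change of 3.24 (log2), and the median was 3.27 and 3.21 under the other 2 scalings of the arrays. All 5 Lce3 genes, late envelope genes of repairing epidermis, had higher values (median 2.31), and 2 of them, Lce3c and Lce3f, passed, while none of 13 Lce1 genes passed (median -0.20). Of 12 kallikrein-related peptidases 6 rose, led by Klk13 at 2.83 (log2), and none fell. Of 22 matrix metalloproteinases 8 rose, led by Mmp13 at 3.04, and none fell, with a median of 0.15 over the family. Of 24 Serpinb genes 3 rose and 4 fell, and of 7 Elovl genes 1 rose and 2 fell. Of 14 S100a genes 3 rose and none fell, while 1 fell after a further quantile normalisation. Rises were also called for 5 of 11 Clec4, 4 of 9 Slfn, 6 of 19 Ms4a and 1 of 6 Siglec genes, with 5 Slfn genes under median centring and 4 Ms4a genes after a further quantile normalisation. Skint genes, which are expressed in epidermis and thymus, had a median of -0.83 over 7 members: 1 fell as deposited, and 2 and 3 fell under median centring and a further quantile normalisation. These counts also depended on single arrays. Without CLEC4C-DTR replicate 1, 5 Lce3 and 6 Serpinb genes rose, 3 Skint genes fell and 1 matrix metalloproteinase fell. With any of the other 5 arrays left out instead, no Lce3 gene passed limma's adjusted p and no Serpinb gene rose past it, although the Lce3 median stayed at 1.73 to 2.38 (log2). Without littermate control replicate 3, 3 Sprr2 and 3 kallikrein genes rose and no matrix metalloproteinase, Clec4 or Slfn gene passed. The Lce1 median turned to 0.24 without CLEC4C-DTR replicate 2 and to 0.07 without littermate control replicate 3.

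Changed genes lay next to each other more often than by chance. Among adjacent genes in RefSeq order (GRCm38.p6) whose symbols do not share their first 3 letters, 153 pairs were called in the same direction against a mean of 74.2 in 10000 shuffles of the calls, a ratio of 2.06 (permutation p = 1e-04, the smallest the shuffles can give). The hypothesis that neighbours of unlike name changed together was met, and shared regulation and shared cell type may each give this. Unlike names do not exclude related genes: Aspn and Ogn, both small leucine-rich proteoglycans, lie in one run below. Related genes may therefore add to this count, which was not tested. Pairs with like names numbered 61 against a mean of 12.8, where shared probes may add to the count. Runs of called neighbours included Optc, Prelp and Fmod, and Ecm2, Aspn, Omd and Ogn, which were lower, and Slamf7, Cd48, Slamf1, Cd84 and Slamf6, which were higher.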
